A study of Mus musculus with 48 samples.

How the data were processed

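Poly(A) RNA from the soma and neurite fractions of CAD cells had been made into 3' end libraries (Lexogen), 48 in all, in 16 groups of 3. Per the labels, the authors trimmed the reads with cutadapt and ran Salmon with the mm10 build. The deposited values used here are estimated counts, the number of reads Salmon assigned to each transcript, which are not normalised. The versions of cutadapt and Salmon and the transcript set are not given in the sources used here. Groups were taken from the labels, which give the rescue line, the dox state (2 ug/mL for 48 hours or none) and the fraction.

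Estimated counts were summed per gene through transcript identifiers in GENCODE M21, an annotation of GRCm38, the assembly that mm10 names. Of 133618 transcripts 133395 were matched, to 52631 genes, and the 223 unmatched ones were left out. Sums were rounded to whole numbers. The total per library ran from 0.0724 to 136.46 M (mega, the SI prefix) estimated reads, and 3 reads correspond to 41.5 CPM in the shallowest library (WT minus dox neurite replicate 1) and to 6.57 CPM in RGG plus dox soma replicate 1. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. The levels of Hnrnpa2b1 and Adgrg1 in CPM were scaled over all 48 libraries, and CPM given for other genes within the libraries of their comparison.

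Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, its filter on low counts, robust quasi-likelihood F tests). P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene passed at an adjusted p under 0.05 with no minimum fold. Neurite against soma, and the change of that ratio with dox, were fitted within each line (12 libraries). The effect of dox, and its difference between lines, were fitted within each fraction (24 libraries). All p-values are 2-sided. Values after ± are standard errors of the log2 fold change, worked back from the F statistic, unless SD is stated. Those of Adgrg1 minus Hnrnpa2b1 ratios and of A2 minus RGG induction combine the errors of both values as if independent.

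In all, 29 gene lists were written before the data were examined, as were the comparisons, the alternatives and the rule for named genes, except where stated. The lists cover hnRNP proteins, kinesins, dynein and dynactin, myosins, motor adaptors and microtubule-associated proteins, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation and mitochondrially encoded mRNAs. They also cover Rab13-like peripheral RNAs, nuclear-enriched long non-coding RNAs, ER chaperones, ATF4 targets, cholesterol synthesis, cell cycle, neuronal genes, postsynaptic and axon guidance genes, and the actin cytoskeleton. The rest are RNA localization and granule proteins, splicing regulators, interferon response, cargos with an A2RE-type element, immediate early genes, p53 targets, glycolysis and hypoxia, and markers of astrocytes, oligodendrocytes, microglia and fibroblasts. Lists of at least 3 measured members were tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2), adjusted over the lists of a comparison, and again with a correlation estimated from the data. Without the comparison of A2 with WT, camera made 206 calls, and 32 with the estimated correlation.

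Genes were named by a rule. Hnrnpa2b1 was named in every comparison. For neurite against soma these were the 12 genes at each end that passed in all 4 lines with a mean of at least 10 CPM. For the other comparisons they were up to 10 genes per direction by fold, with at least 10 CPM and, for dox effects, no overlap between the libraries of the 2 states. Genes that passed in 3 or more lines, up to 10 per direction, and up to 4 members of each list were added, and unnamed gene models were skipped. Some genes that the rule names are not reported here. The comparison of the A2 with the WT line, and leaving out the 2 libraries under 1 M reads, were chosen after seeing the data.

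The alternatives were RLE factors, no filter on low counts, DESeq2 1.42.0, 1 fit of all 48 libraries, the replicate numbers as a block, fry for the lists, and leaving out each library in turn. Motifs in 3' UTRs of at least 50 nt were compared by a permutation test of the difference of medians (100000 resamples). Whether equal replicate numbers pair libraries was checked by correlating, across genes, the deviations of 2 libraries from their group means. Every r was above 0.1 for B1 soma with neurite (0.156 to 0.655), and for minus with plus dox in B1 soma (0.131 to 0.638), A2 neurites (0.251 to 0.353) and RGG neurites (0.127 to 0.366). Elsewhere it went as low as -0.195. Still, 17 of 24 soma and neurite pairs and 14 of 24 minus and plus dox pairs correlated best with their own number. For A2 soma with neurite this held in 5 of 6 (r up to 0.63). Some comparisons fitted as unpaired may therefore be paired in part. For the results where every r was above 0.1, the value with the block is given where it changed a call or moved a count by more than 1.5 times. Genes are not independent replicates, so these r values are across genes only.

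The test was also tested on simulated data, built from these libraries with 200 genes changed and each gene drawn independently. In the real comparison of dox in A2 soma 7203 of 15148 genes passed, so the shares below may not carry over to the real data. For dox in A2 soma, 41.5, 71.9 and 80 percent of changes of 1.5, 2 and 4-fold were recovered. For the change of the ratio in WT these shares were 3.2, 19.3 and 62.2 percent, with 7.8 percent of the calls false. For the difference between A2 and B1 in soma they were 14.8, 51.7 and 74 percent, with 7 percent false, and for WT against RGG in neurites 4.1, 19.7 and 60.4 percent, with 4 percent false. For the change of the ratio in A2, 11.8 percent of the calls were false, more than the 5 percent the threshold allows.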

Results

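RNA was profiled in the cell body (soma) and neurite fractions of CAD cells, a mouse neuronal line with catecholaminergic features that grows neurites when serum is taken away. The study concerns HNRNPA2B1, an RNA-binding protein whose gene gives the A2 and B1 isoforms. There were 4 rescue lines, named here by their labels: HNRNPA2 rescue (the A2 line), HNRNPB1 rescue (the B1 line), WT HNRNPA2 rescue (the WT line) and RGG mutant HNRNPA2 rescue (the RGG line). Each line was kept without doxycycline (dox) or given 2 ug/mL for 48 hours to switch the rescue on. With 4 lines, 2 dox states and 2 fractions there were 16 groups of 3 libraries, 48 in all. Library totals ran from 0.0724 M (mega, the SI prefix) estimated reads (WT minus dox neurite replicate 1) to 136.46 M (RGG minus dox soma replicate 1), with a median of 12.755 M. RGG plus dox soma replicate 1, at 0.4568 M, was the other library under 1 M reads. The labels do not say that the 3 replicates of a group are separate cultures, so the p-values measure the spread between these libraries, which may be technical. Every value below rests on n = 3 libraries per group unless stated.

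The induced gene was looked at first, since its level checks the dox labels, though not which rescue a line carries. Hnrnpa2b1 (ENSMUSG00000004980.16) is a protein-coding gene on chromosome 6 of GRCm38, from 51460932 to 51469894 on the minus strand. In soma its level rose with dox from 77.4 ± 1.8 to 734 ± 140 CPM (counts per M reads, mean ± SD) in the A2 line and from 77.3 ± 7.2 to 704 ± 79 CPM in the B1 line. It rose from 84 ± 9.5 to 517 ± 66 CPM in the WT line and from 83 ± 4.9 to 729 ± 82 CPM in the RGG line. In neurites the plus dox means were 1080 ± 100, 905 ± 40, 751 ± 150 and 768 ± 150 CPM in the A2, B1, WT and RGG lines, against 102 ± 6.8, 115 ± 12 and 114 ± 10 CPM without dox in the first 3. No minus dox neurite library was above 137 CPM. As log2 fold changes of Hnrnpa2b1 these rises were 3.22 ± 0.14 (SE), 3.13 ± 0.14, 2.63 ± 0.13 and 3.14 ± 0.14 in soma. In neurites they were 3.42 ± 0.18, 2.97 ± 0.18, 2.66 ± 0.19 and 2.64 ± 0.17, and the largest edgeR adjusted p was 3.5e-10. The effect of dox on the neurite to soma ratio of Hnrnpa2b1 itself did not pass in any line, at 0.20 ± 0.17 (adjusted p = 0.591) in A2, -0.15 ± 0.16 (0.611) in B1, 0.02 ± 0.25 (1) in WT and -0.48 ± 0.24 (1) in RGG. In soma 1 protein-coding transcript of Hnrnpa2b1 went from 0.668 to 62.1 percent of the gene's reads with dox in A2. It went from 0 to 29.6 percent in WT and to 28.2 percent in RGG. In B1 it stood at 0.0446 percent with dox, while a nonsense-mediated decay transcript went from 1.19 to 55.8 percent. This split set B1 apart, though how 3' end reads divide among transcripts is uncertain. The ratios with and without dox may thus not be of the same RNA. In Hnrnpa2b1 level all 24 plus dox libraries lay above all 24 minus dox libraries of the same fraction. Reads from the 3' end of a gene can lie outside its altered part, so the reads left without dox say nothing about loss of the protein.

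**Figure D1:**
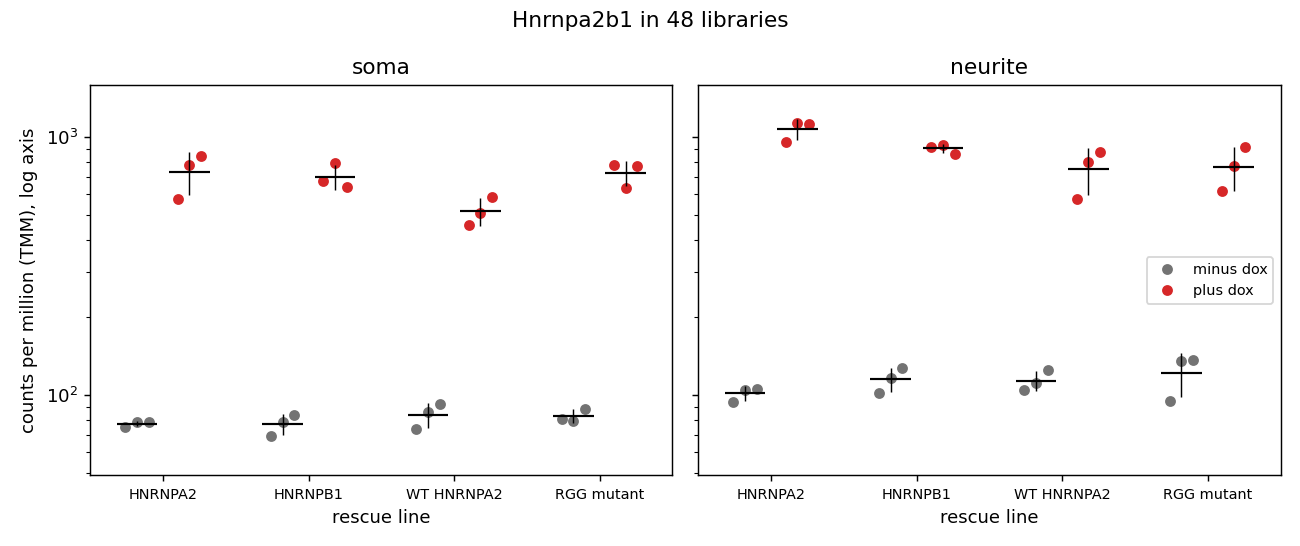
Hnrnpa2b1 in each of the 48 libraries, in TMM-scaled CPM on a log axis, for soma (left) and neurites (right) of the 4 rescue lines. Points are libraries, bars are means and vertical lines are ± 1 SD of 3 libraries; in soma the plus dox means (517 to 734) lie above the minus dox means (77.3 to 84).

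Which RNAs were held in neurites rather than soma was asked within each line, over the minus dox and plus dox libraries together. Among genes the naming rule allows, and by the mean over the lines, neurite libraries were richest relative to soma in Trp53inp2. This regulator of autophagy had log2 ratios of 5.64 ± 0.16, 5.76 ± 0.25, 4.64 ± 0.24 and 3.81 ± 0.41 in the A2, B1, WT and RGG lines. Trak2, an adaptor that ties mitochondria to kinesin, had ratios of 5.28 ± 0.13, 5.48 ± 0.41, 3.84 ± 0.18 and 2.94 ± 0.43. Cplx2, a SNARE-binding synaptic protein, followed with 4.75 ± 0.13, 4.77 ± 0.25, 4.10 ± 0.20 and 3.65 ± 0.34. Net1, an exchange factor for RhoA, had 4.91 ± 0.16, 5.27 ± 0.29, 3.80 ± 0.13 and 3.13 ± 0.32. Nes, which encodes the intermediate filament nestin, had 4.35 ± 0.12, 4.58 ± 0.21, 3.44 ± 0.24 and 2.80 ± 0.30. Akap12, an anchor for protein kinase A, had 3.90 ± 0.14, 4.71 ± 0.26, 3.43 ± 0.22 and 2.35 ± 0.37. The other genes the rule named at the neurite end were Sh3pxd2a (2.89 to 4.93 over the 4 lines), the growth factor gene Gdf11 (3.18 to 4.41), Cdc42bpg (2.65 to 4.48), Cdk15 (3.32 to 4.02) and Lhfpl4 (2.98 to 3.87). Reads assigned to Mir6236, annotated as a microRNA gene, gave ratios of 3.02 to 4.51 with errors of 0.81 to 1.32. Which RNA these poly(A) libraries picked up there was not tested. Hnrnpa2b1 was higher in neurites in A2, B1 and WT (0.47 ± 0.09, 0.47 ± 0.08 and 0.53 ± 0.12) and did not pass in RGG (0.32 ± 0.12, edgeR adjusted p = 0.0539).

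Among genes the naming rule allows, and by the mean over the lines, soma libraries were richest relative to neurites in Lnpep. This membrane aminopeptidase had log2 ratios of -2.23 ± 0.10, -1.93 ± 0.11, -1.80 ± 0.15 and -2.06 ± 0.20. Xist, the non-coding RNA that coats the inactive X chromosome, had ratios of -2.09 ± 0.10, -1.97 ± 0.13, -1.83 ± 0.13 and -1.69 ± 0.13. The giant cadherin Fat1 had -1.58 ± 0.09, -1.71 ± 0.14, -1.86 ± 0.14 and -1.74 ± 0.19. Spen, a transcriptional repressor, had -1.74 ± 0.07, -1.97 ± 0.08, -1.67 ± 0.11 and -1.48 ± 0.12. Ep300, a histone acetyltransferase, had -1.40 ± 0.05, -1.59 ± 0.07, -1.52 ± 0.10 and -1.69 ± 0.13. Lcor (-2.11 to -1.40), Zfp871 (-1.96 to -1.50), Soga1 (-1.66 to -1.51), Adcy9 (-1.72 to -1.36) and Dchs1 (-1.71 to -1.42) were also lower in neurites in all 4 lines. Pcdhgb1 (-2.13 to -1.42) and Pcdhgb8 (-2.00 to -1.44) belong to a cluster of genes with common 3' exons, so the split of reads between its members is uncertain.

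Ribosomal protein mRNAs were higher in neurites for 81, 81, 80 and 76 of the 81 measured members in the A2, B1, WT and RGG lines (81, 81, 81 and 79 adjusted over the list alone). Their median log2 ratios were 1.76, 1.97, 1.37 and 1.09. As a set they were called by camera in all 4 lines (adjusted p = 1.1e-53 to 2.1e-29), with adjusted p = 0.263, 0.474, 0.0262 and 0.0233 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, and how reads were divided among them is uncertain. Nuclear genes of oxidative phosphorylation were higher for 79 of 83, 81 of 83, 74 of 84 and 71 of 83 members (79, 81, 75 and 75 adjusted over the list alone; camera adjusted p = 0.21, 0.219, 0.023 and 0.0233 with an estimated correlation). Mitochondrial ribosomal protein genes were higher for 78, 76, 68 and 50 of 78 (78, 77, 73 and 56 over the list alone; 0.21, 0.0738, 0.0967 and 0.0201 with an estimated correlation). The 13 mRNAs encoded in the mitochondrial genome were higher for 13, 13, 12 and 8 members (13, 13, 13 and 10 over the list alone; 0.21, 0.511, 0.116 and 0.387 with an estimated correlation). A list of 17 RNAs found at the periphery of cells together with Rab13 was fixed beforehand, and 13, 12, 13 and 12 of them were higher in neurites and 4, 4, 3 and 4 lower (over the list alone 13, 13, 13 and 12 higher; 0.21, 0.511, 0.0295 and 0.388 with an estimated correlation). Rab13, a small GTPase, had log2 ratios of 3.53 ± 0.12, 3.65 ± 0.22, 3.40 ± 0.21 and 2.84 ± 0.25.

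Actin cytoskeleton genes were higher in neurites for 25, 24, 18 and 12 of 35 members and lower for 3, 3, 6 and 6 (over the list alone 26, 24, 18 and 15 higher). As a set they were called in A2, B1 and WT (camera adjusted p = 6.7e-06, 8.5e-05 and 3.3e-04, or 0.21, 0.0803 and 0.482 with an estimated correlation) and not in RGG (0.195). Postsynaptic and axon guidance genes were lower in neurites for 17 of 31, 20 of 31, 15 of 32 and 12 of 31 members (17, 22, 15 and 12 over the list alone; adjusted p = 0.21, 0.0738, 0.661 and 0.241 with an estimated correlation). Of 40, 39, 38 and 38 kinesin genes measured, 11, 13, 9 and 9 were higher in neurites and 9, 9, 8 and 4 lower (11, 13, 9 and 9 higher over the list alone). Their median ratio (-0.07, 0.02, -0.10 and -0.08) and mean ratio (0.34, 0.47, 0.28 and 0.24) differed in sign in A2, WT and RGG. Camera did not call the kinesin set (adjusted p = 0.42, 0.335, 0.157 and 0.34). Over all genes tested, 8636 of 14988 passed in the A2 line (4120 higher and 4516 lower in neurites), 8486 of 13967 in B1 (3981 and 4505), 6306 of 14179 in WT (3126 and 3180) and 3730 of 13138 in RGG (1673 and 2057). In all 4 lines 1488 were higher and 1761 lower.

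The effect of dox on soma RNA was tested as plus dox against minus dox within each line. Every plus dox library came from a line with a rescue. An effect of dox itself therefore cannot be told apart from one of the rescue protein in any dox result below. The A2 and B1 lines showed a rise of endoplasmic reticulum (ER) stress genes and a fall of neuronal and cholesterol synthesis genes. Hspa5, the main ER chaperone, rose by a log2 fold change of 2.90 ± 0.16 in A2 (TMM-scaled CPM 732 to 5450) and 1.87 ± 0.15 in B1 (839 to 3070). Ppp1r15a, a phosphatase subunit that reverses the block on translation under stress, rose by 4.24 ± 0.15 and 3.86 ± 0.15. The stress transcription factors Ddit3 (3.38 ± 0.13 and 3.39 ± 0.13) and Atf3 (3.48 ± 0.21 and 3.06 ± 0.22), the pseudokinase Trib3 (2.26 ± 0.16 and 2.47 ± 0.17) and the haem oxygenase Hmox1 (2.99 ± 0.28 and 2.92 ± 0.29) also rose. The antiviral gene Rsad2 rose by 5.97 ± 0.40 and 3.14 ± 0.40, Cmya5 by 4.96 ± 0.43 and 3.70 ± 0.44, and Lhfpl2 by 4.60 ± 0.27 and 4.17 ± 0.28. Falls were led by Rgs4, a brake on G protein signalling (-4.17 ± 0.31 and -3.98 ± 0.31), Pirt (-4.03 ± 0.17 and -4.22 ± 0.17), Sgpp2 (-3.94 ± 0.24 and -4.13 ± 0.25) and Ptprr (-3.59 ± 0.16 and -2.99 ± 0.16). Dbh, which makes noradrenaline, followed (-3.53 ± 0.24 and -3.59 ± 0.28), with Angpt2 (-3.51 ± 0.28 and -3.78 ± 0.30), the receptor gene Igf2r (-3.39 ± 0.13 and -3.12 ± 0.13) and the adrenergic receptor gene Adra2b (-3.25 ± 0.17 and -3.27 ± 0.18).

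Of 25 ER chaperone and unfolded protein response genes measured, 23 rose in A2 and 19 in B1, where 2 fell (23 rose in A2, 21 rose and 2 fell in B1 adjusted over the list alone). Camera gave adjusted p = 3.4e-15 and 1.6e-07, or 0.0353 and 0.18 with an estimated correlation. Besides Hspa5, Sdf2l1 rose by 2.27 ± 0.14 and 1.32 ± 0.14, Manf by 1.61 ± 0.24 and 1.05 ± 0.24, and Hsp90b1 by 1.11 ± 0.12 and 0.40 ± 0.12. Of 28 targets of the transcription factor ATF4, 13 rose and 3 fell in A2, and 19 rose in B1 (14 and 3, then 19 and 1, over the list alone; camera adjusted p = 0.17 and 0.0292 with an estimated correlation). All 24 measured cholesterol synthesis genes fell in A2 and in B1 (24 and 24 over the list alone), with medians of -1.33 and -1.15 and camera adjusted p = 0.0199 and 0.0141 with an estimated correlation. Among them were Hmgcs1 (-1.66 ± 0.11 and -1.54 ± 0.11) and Idi1 (-1.68 ± 0.12 and -1.5 ± 0.12). Of 40 neuronal genes, 34 fell and 1 rose in A2 and 33 fell and 1 rose in B1 (34 and 33 fell over the list alone; medians -1.22 and -1.02; camera adjusted p = 0.0148 and 0.0141 with an estimated correlation). The synaptic vesicle genes Syn2 (-2.76 ± 0.11 and -2.42 ± 0.11) and Syt1 (-1.92 ± 0.09 and -1.64 ± 0.09) were among them. So were the neuronal tubulin gene Tubb3 (-2.05 ± 0.09 and -1.60 ± 0.09), the growth cone gene Gap43 (-1.57 ± 0.12 and -1.38 ± 0.12) and the granin Chga (-1.91 ± 0.14 and -1.92 ± 0.14). Postsynaptic and axon guidance genes fell for 22 and 17 of 31 and rose for 4 and 3 (23 and 18 fell over the list alone; adjusted p = 0.0148 and 0.0141 with an estimated correlation). Motor adaptor and microtubule-associated protein genes fell for 22 and 22 of 37 and rose for 4 and 4 (22 and 22 fell over the list alone; 0.0353 and 0.0341 with an estimated correlation). Interferon response genes rose for 16 and 10 of 30 and fell for 4 and 1 (16 and 10 rose over the list alone; camera adjusted p = 0.0163 and 0.0231, or 0.443 and 0.529 with an estimated correlation).

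In the WT and RGG lines glycolysis and hypoxia genes fell in soma, as in A2 and B1, while few of the ER stress genes that rose in A2 and B1 passed. Ndrg1, a hypoxia-responsive gene, fell with log2 fold changes of -2.57 ± 0.34 in WT and -3.86 ± 0.44 in RGG. The mitophagy gene Bnip3 (-2.32 ± 0.38 and -3.47 ± 0.45), the lactate exporter gene Slc16a3 (-2.07 ± 0.31 and -4.02 ± 0.37) and Txnip, which is sensitive to glucose (-2.06 ± 0.18 and -2.91 ± 0.22), fell as well. So did Ak4 (-1.88 ± 0.27 and -2.65 ± 0.33), Ankrd37 (-2.09 ± 0.32 and -2.77 ± 0.38), Kbtbd11 (-2.83 ± 0.53 and -4.30 ± 0.69) and the synuclein gene Sncb (-2.61 ± 0.33 and -3.27 ± 0.40). Thy1, a surface glycoprotein of neurons, rose by 3.74 ± 0.41 and 2.91 ± 0.45, and the transcription factor gene Ets2 by 1.74 ± 0.13 and 1.35 ± 0.13. Hspa5 did not pass, at 0.11 ± 0.15 (adjusted p = 0.726) in WT and -0.23 ± 0.15 (0.353) in RGG. Of the 25 ER chaperone and unfolded protein response genes, 5 rose in WT, Sdf2l1 (0.71 ± 0.14) among them, and 2 rose and 2 fell in RGG (8 rose and 1 fell in WT, 2 and 2 in RGG, over the list alone). Camera called the set in WT (adjusted p = 4.5e-04, or 0.542 with an estimated correlation) and not in RGG (0.814). Ppp1r15a, at -0.35 ± 0.14 (0.139) in WT, and Ddit3, at -0.24 ± 0.13 (0.3), did not pass. In RGG Ppp1r15a (-0.93 ± 0.17) and Ddit3 (-0.67 ± 0.15) fell. Cholesterol synthesis genes fell for 3 and rose for 1 of 24 in WT and fell for 18 in RGG (6 and 19 fell over the list alone; camera adjusted p = 0.0162 and 9.1e-11, or 0.724 and 0.131 with an estimated correlation). Of 40 neuronal genes, 6 fell and 3 rose in WT and 12 fell and 3 rose in RGG (8 and 6, then 14 and 7, over the list alone), and camera did not call the set in either line. Immediate early genes fell for 10 of 25 in WT and 9 in RGG, with 1 rising in each (11 and 13 fell over the list alone; adjusted p = 0.0575 and 0.162 with an estimated correlation).

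The fall of glycolysis and hypoxia genes was called in all 4 lines: 27 of 32 fell in A2, 26 in B1, 28 in WT and 29 in RGG, and 0 rose in any line (27, 28, 28 and 31 fell over the list alone). The medians were -1.18, -0.93, -1.10 and -1.48, with camera adjusted p = 0.245, 0.261, 0.044 and 0.112 with an estimated correlation. Pgk1, a glycolytic kinase, had log2 fold changes of -1.24 ± 0.18, -1.12 ± 0.18, -1.59 ± 0.18 and -2.17 ± 0.20. Pdk1, which holds pyruvate back from mitochondria, had -2.15 ± 0.20, -2.00 ± 0.20, -1.62 ± 0.20 and -2.5 ± 0.23. Rgs4 (-1.52 ± 0.28 and -2.48 ± 0.31), Dbh (-1.49 ± 0.20 and -3.65 ± 0.26) and the gap junction gene Gjd2 (-1.25 ± 0.22 and -2.28 ± 0.26) fell in WT and RGG too. Genes that rose in all 4 lines were led by Adgrg1, an adhesion receptor gene on chromosome 8 (94974751 to 95014217, plus strand), with log2 fold changes of 6.62 ± 0.15, 6.17 ± 0.15, 6.61 ± 0.15 and 6.72 ± 0.16. Its mean rose from 2.31 to 233, from 3.39 to 247, from 2.48 to 237 and from 2.79 to 274 CPM. The matrix protease gene Mmp9 rose by 2.28 ± 0.25, 2.18 ± 0.26, 2.17 ± 0.26 and 3.53 ± 0.29. Nabp1 rose by 1.74 ± 0.13, 1.83 ± 0.13, 1.33 ± 0.13 and 1.14 ± 0.13. S100pbp rose by 1.27 ± 0.12, 1.48 ± 0.12, 1.56 ± 0.12 and 1.68 ± 0.12.

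**Figure D2:**
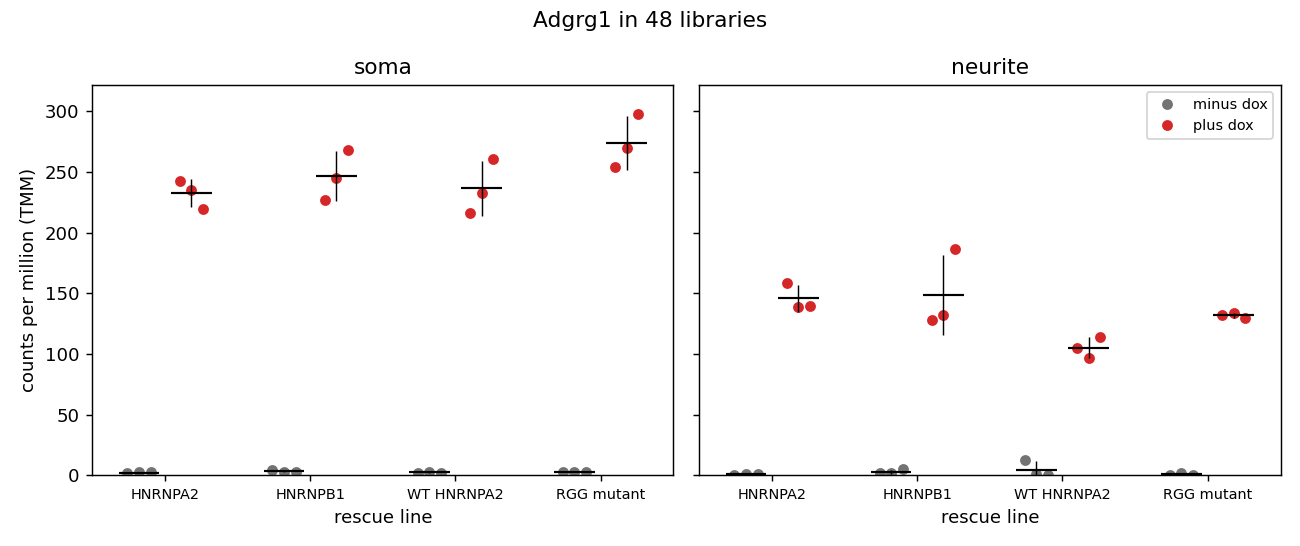
Adgrg1 in each of the 48 libraries, in TMM-scaled CPM on a linear axis from 0, for soma (left) and neurites (right) of the 4 rescue lines. Points are libraries, bars are means and vertical lines are ± 1 SD of 3 libraries; the plus dox means in soma are 233 to 274 and in neurites 105 to 149, while minus dox libraries are at 4.93 or less except WT neurite replicate 1, where 1 read is 13.1 CPM.

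Over all 15148 genes tested in soma, 7203 passed in A2 (3493 rose and 3710 fell), 5766 in B1 (2678 and 3088), 1249 in WT (593 and 656) and 1675 in RGG (728 and 947). A2 and B1 shared 2389 that rose and 2737 that fell, against 617.5 and 756.3 for independent lists, and 1 gene went opposite ways. WT and RGG shared 216 and 317, against 28.5 and 41 for independent lists. A2 and WT shared 164 and 338, against 136.7 and 160.7, with 390 going opposite ways. In 3 or more lines 276 rose and 599 fell, and in all 4 lines 55 rose and 192 fell. The WT count was 765 without minus dox replicate 1, 731 without minus dox replicate 2, 702 without plus dox replicate 2 and 816 without plus dox replicate 3. The balance of rises and falls in WT depended on the processing. It was 350 and 724 without the filter on low counts, 473 and 751 with RLE factors and 616 and 899 with DESeq2.

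**Figure D3:**
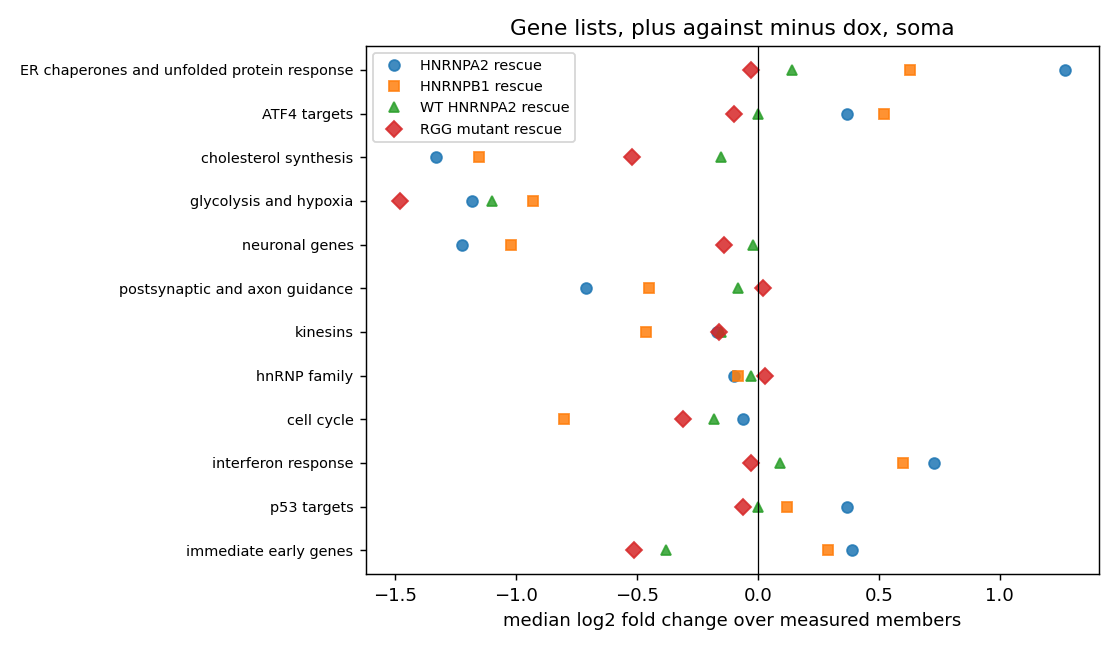
Median log2 fold change, plus against minus dox in soma, over the measured members of 12 gene lists (vertical axis), 1 symbol per rescue line and a line at 0. ER chaperone genes lie at 1.27 in A2 and 0.63 in B1, cholesterol synthesis genes at -1.33 and -1.15, and glycolysis and hypoxia genes at -1.18, -0.93, -1.10 and -1.48 in A2, B1, WT and RGG.

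The same test in neurites gave large falls of Akap12 and of several kinesin RNAs. Akap12 fell from 30100 to 1240 TMM-scaled CPM in A2, a log2 fold change of -4.60 ± 0.56, with -3.86 ± 0.54, -2.21 ± 0.51 and -4.22 ± 0.55 in B1, WT and RGG. The axonal kinesin gene Kif1a fell from 10900 to 663 CPM in A2 (-4.04 ± 0.57), with -3.82 ± 0.56, -2.23 ± 0.52 and -3.79 ± 0.56 in B1, WT and RGG. Kif5a, a kinesin-1 heavy chain gene, had -4.01 ± 0.34, -4.09 ± 0.34, -1.91 ± 0.32 and -2.40 ± 0.32. Kif5c fell in A2, B1 and RGG (-3.98 ± 0.57, -3.53 ± 0.56 and -3.39 ± 0.56) and did not pass in WT (-1.80 ± 0.52, edgeR adjusted p = 0.0949). The vesicle priming gene Unc13c had -5.37 ± 0.47, -5.26 ± 0.46, -1.86 ± 0.43 and -3.85 ± 0.51. The kinase gene Prkd1 had -4.72 ± 0.35, -4.10 ± 0.34, -1.68 ± 0.35 and -3.12 ± 0.40. Grap2 (-4.82 ± 0.35) and Ptgfr (-4.23 ± 0.39) fell in A2, and Fan1 (-3.81 ± 0.56) in RGG. Synm, an intermediate filament gene, fell in A2, B1 and RGG (-4.17 ± 0.55, -3.85 ± 0.54 and -3.47 ± 0.54). In WT and RGG, Mcf2l, a guanine nucleotide exchange factor gene (-2.15 ± 0.46 and -4.59 ± 0.58), and Sncb (-2.28 ± 0.26 and -2.78 ± 0.28) fell. Fyco1, an adaptor between vesicles and kinesin, fell there too (-1.97 ± 0.43 and -3.62 ± 0.46). Genes that rose in A2 and B1 included Ppp1r15a at 4.33 ± 0.21 and 3.76 ± 0.21, Ddit3 at 3.44 ± 0.16 and 3.02 ± 0.16, and Hspa5 at 3.02 ± 0.22 and 2.18 ± 0.21. Adgrg1 rose by 6.99 ± 0.36 in A2 and 5.56 ± 0.32 in B1. It also rose in WT and RGG, where the minus dox libraries held 1, 7 and 0 reads and 0, 12 and 6 reads, so no fold is given. In all 4 lines S100pbp rose by 1.59 ± 0.13, 1.77 ± 0.13, 1.82 ± 0.14 and 1.93 ± 0.13. Nabp1 rose by 1.72 ± 0.16, 1.91 ± 0.17, 1.74 ± 0.20 and 1.60 ± 0.17. Ets2 (1.75 ± 0.17) and Thy1 (2.36 ± 0.41) rose in WT.

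The share of reads in mitochondrially encoded mRNAs was higher in neurites than in soma and moved with dox. It went from 17.2 ± 0.98 to 7.04 ± 0.6 percent (mean ± SD) in A2 neurites and from 19.6 ± 0.15 to 8.35 ± 2.8 percent in B1, where plus dox replicates 1, 2 and 3 stood at 10.4, 9.48 and 5.17 percent. In WT it went from 9.43 ± 1.6 to 5.81 ± 0.89 percent and in RGG from 8.03 ± 1.3 to 5.7 ± 1.1 percent. Of the 13 such mRNAs, 12, 12, 4 and 2 fell in neurites of A2, B1, WT and RGG (13, 12, 9 and 5 adjusted over the list alone), and 0 rose. The medians were -1.85, -1.85, -0.81 and -0.42, with camera adjusted p = 0.13, 0.0947, 0.226 and 0.403 with an estimated correlation. The mRNA mt-Co1, for a subunit of cytochrome oxidase, had -2.10 ± 0.29, -2.22 ± 0.30, -1.17 ± 0.29 and -1.35 ± 0.29. In soma 1, 5, 0 and 0 of the 13 fell and 0 rose (0, 5, 0 and 0 over the list alone; in B1 the camera adjusted p was 0.0769, and 0.0218 with the replicate numbers as a block). Nuclear genes of oxidative phosphorylation fell in neurites for 63, 67, 6 and 17 of 84, and 1 rose, in RGG (65, 70, 7 and 19 fell over the list alone; adjusted p = 0.0601, 0.0154, 0.226 and 0.163 with an estimated correlation). Ribosomal protein genes fell for 53, 69, 6 and 28 of 81, and 1 rose, in A2 (57, 76, 24 and 60 fell over the list alone; 0.308, 0.103, 0.226 and 0.163 with an estimated correlation). Without the 2 libraries under 1 M reads, 0 of 81 fell in WT and 42 in RGG.

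**Figure D4:**
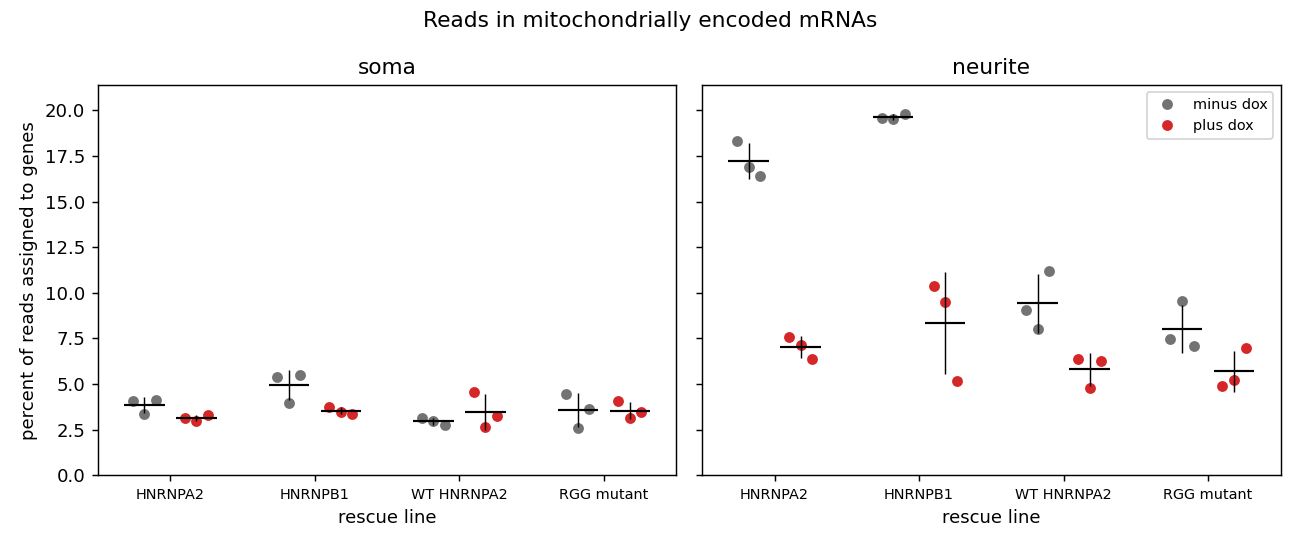
Percent of reads in mitochondrially encoded mRNAs in each of the 48 libraries, on a linear axis from 0, for soma (left) and neurites (right) of the 4 rescue lines. Points are libraries, bars are means and vertical lines are ± 1 SD of 3 libraries; neurite means go from 17.2, 19.6, 9.43 and 8.03 percent without dox to 7.04, 8.35, 5.81 and 5.7 percent with dox in A2, B1, WT and RGG.

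Among 39 kinesin genes measured in neurites, 17, 21, 7 and 13 fell in A2, B1, WT and RGG, and 2 and 3 rose in A2 and B1 (17, 22, 11 and 15 fell over the list alone). Camera called the set in each line (adjusted p = 1.8e-04, 2.9e-07, 1.5e-04 and 2.6e-10, or 0.262, 0.114, 0.313 and 0.153 with an estimated correlation). Of the 17 Rab13-like peripheral RNAs, 11, 10, 5 and 12 fell, and 2 rose in each of A2 and B1 (11, 11, 10 and 13 fell over the list alone; 0.254, 0.104, 0.0991 and 0.00947 with an estimated correlation). Rab13 fell in A2, B1 and RGG (-3.44 ± 0.33, -3.14 ± 0.33 and -2.41 ± 0.34) and did not pass in WT (-1.22 ± 0.33, edgeR adjusted p = 0.0726). Motor adaptor and microtubule-associated protein genes fell for 21, 23, 5 and 10 of 36 and rose for 4, 4, 1 and 2 (24, 24, 7 and 12 fell over the list alone; 0.0295, 0.0154, 0.239 and 0.201 with an estimated correlation). Neuronal genes fell for 34, 31, 5 and 6 of 39 and rose for 2, 1, 1 and 2 (34, 33, 5 and 9 fell over the list alone; 8.7e-04, 0.00151, 0.226 and 0.25 with an estimated correlation). Cholesterol synthesis genes fell for 24, 21, 1 and 4 of 24 (24, 21, 1 and 6 over the list alone), with adjusted p = 0.00637, 0.0122 and 0.295 in A2, B1 and RGG with an estimated correlation and no camera call in WT. ER chaperone genes rose for 22, 21, 0 and 1 of 25, and 1 fell, in B1 (22, 22, 0 and 0 rose over the list alone; 0.0601 and 0.0947 in A2 and B1 with an estimated correlation). In WT, where 0 rose by edgeR, the camera adjusted p was 0.907. Glycolysis and hypoxia genes fell for 21, 21, 23 and 27 of 31 (23, 22, 27 and 29 over the list alone; 0.119, 0.103, 0.0251 and 0.00377 with an estimated correlation).

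Over the 14374 genes tested in neurites, 6278 passed in A2 (3150 rose and 3128 fell), 5255 in B1 (2533 and 2722), 297 in WT (68 and 229) and 1435 in RGG (650 and 785). A2 and B1 shared 2193 that rose and 2329 that fell (555.1 and 592.3 for independent lists), and WT and RGG shared 37 and 201 (3.1 and 12.5). In 3 or more lines 130 rose and 519 fell, and in all 4 lines 12 rose and 174 fell. The WT count was 455 without minus dox replicate 2, 98 without minus dox replicate 3, 164 without plus dox replicate 2 and 171 without plus dox replicate 3, and the RGG count was 898 without plus dox replicate 1. Reads in the satellite-type gene models Gm10800, Gm10801 and Gm10717 stood at 64.2, 205 and 2160 CPM in RGG plus dox neurite replicates 1, 2 and 3 and at 0 in the RGG minus dox neurite libraries. They stood at 2170 CPM in WT minus dox neurite replicate 1.

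Whether dox changed the neurite to soma ratio of an RNA was tested as an interaction within each line. Several kinesin RNAs and RNAs of the cell periphery had ratios that fell. Genes outside the Rab13-like list, but with a like ratio without dox, fell as well (median changes -1.76, -1.28, -1.22 and -1.88 in A2, B1, WT and RGG). These genes were picked by the same minus dox ratios that enter their change, which can make their fall too large. Kinesin genes were not matched and were not taken out of them. Whether the fall is particular to kinesin or peripheral RNAs is therefore not decided. Kif5b, a kinesin-1 heavy chain gene on chromosome 18 (6201002 to 6242174, minus strand), had log2 changes of the ratio of -3.93 ± 0.23 in A2, -3.44 ± 0.38 in B1 and -3.06 ± 0.39 in RGG. In WT Kif5b did not pass (-1.88 ± 0.46, edgeR adjusted p = 0.21). Apc, a microtubule-binding protein that anchors peripheral RNAs (chromosome 18, 34220924 to 34322552), had -3.73 ± 0.17, -3.37 ± 0.27 and -3.20 ± 0.55 in A2, B1 and RGG. In WT Apc did not pass (-1.55 ± 0.34, 0.0943). Akap12 (chromosome 10, 4266380 to 4359470) had -3.85 ± 0.26, -3.12 ± 0.45 and -2.42 ± 0.40 in A2, B1 and WT, and did not pass in RGG (-4.13 ± 0.73, 0.0674). Kif1b fell in A2, B1 and RGG (-3.54 ± 0.21, -3.23 ± 0.30 and -2.75 ± 0.34) and Kif1a in A2, B1 and WT (-3.21 ± 0.24, -2.90 ± 0.50 and -2.02 ± 0.36). Kif5c fell in A2 and B1 (-3.31 ± 0.22 and -2.51 ± 0.53). The kinesin light chain genes Klc1 and Klc2 passed in all 4 lines, Klc1 with -2.33 ± 0.17, -2.70 ± 0.15, -1.71 ± 0.25 and -1.88 ± 0.31. Klc2 had -1.98 ± 0.14, -2.37 ± 0.14, -1.32 ± 0.24 and -1.48 ± 0.23. Klc4 passed in A2, B1 and RGG (-2.33 ± 0.20, -3.09 ± 0.15 and -2.13 ± 0.33) and not in WT (-1.60 ± 0.45, edgeR adjusted p = 0.365).

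Prkd1 (-4.66 ± 0.34 and -4.16 ± 0.25 in A2 and B1) and Phactr2 (-3.48 ± 0.17, -3.66 ± 0.26 and -2.81 ± 0.27 in A2, B1 and RGG) had ratios that fell. So did Unc13c (-3.92 ± 0.45), Prkd3 (-3.63 ± 0.36) and Nes (-3.31 ± 0.22) in A2. In RGG the ratios of Fyco1 (-3.98 ± 0.66), Mcf2l (-3.77 ± 0.59), Cdk15 (-3.22 ± 0.49) and Specc1 (-3.17 ± 0.58) fell. Ncl, which encodes nucleolin, had -2.59 ± 0.24, -2.32 ± 0.40, -1.69 ± 0.28 and -3.14 ± 0.34, and passed in all 4 lines. Anp32b (-2.41 ± 0.20, -2.35 ± 0.27, -1.89 ± 0.27 and -2.74 ± 0.40) and the reductase gene Cyb5r3 (-2.55 ± 0.19, -2.40 ± 0.25, -2.07 ± 0.39 and -2.76 ± 0.50) did as well. Net1 (-1.86 ± 0.24) and Trak2 (-1.83 ± 0.32) fell in WT. The rises were smaller, with 10 genes past 2-fold in A2 and 31 in B1, against 245 and 264 falls. Among genes that the naming rule allows, the rises in A2 were led by Mfap2 (0.80 ± 0.19), the splicing factor gene Srrm2 (0.79 ± 0.13) and Polr2a (0.74 ± 0.15). Polr2a encodes the largest subunit of RNA polymerase II. Under the same rule the rises in B1 were led by Adnp (1.29 ± 0.15), Lrp5 (1.14 ± 0.17) and Ptprn2 (1.04 ± 0.20).

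Of the 17 Rab13-like RNAs, 11, 8, 5 and 4 had a ratio that fell in A2, B1, WT and RGG, and 2 rose in B1 (11, 10, 10 and 12 fell adjusted over the list alone). The median change was -1.70, -1.68, -1.19 and -1.64, with camera adjusted p = 3.3e-16, 1.7e-06, 1.6e-17 and 4.2e-16, or 0.0453, 0.261, 0.0229 and 0.111 with an estimated correlation. Their median log2 ratio of neurite to soma went from 2.60 to 0.88 in A2, from 2.95 to 1.24 in B1, from 1.97 to 1.07 in WT and from 1.92 to 0.37 in RGG. Rab13 fell in A2 and B1 (-2.71 ± 0.23 and -2.79 ± 0.43), and did not pass in WT (-1.5 ± 0.40, edgeR adjusted p = 0.279) or RGG (-2.27 ± 0.48, 0.0608). Dynll2, a dynein light chain gene, fell in A2, B1 and RGG (-2.74 ± 0.18, -2.80 ± 0.23 and -2.04 ± 0.35) and did not pass in WT (-1.02 ± 0.34, 0.445). Of the kinesin genes, 9, 12, 4 and 6 had a ratio that fell and 0 rose (13, 15, 9 and 9 fell and 1 and 3 rose, in A2 and B1, over the list alone; adjusted p = 0.057, 0.207, 0.482 and 0.219 with an estimated correlation). The mitochondrially encoded mRNAs, whose share of neurite reads fell as given above, had a ratio that fell for 12, 8, 0 and 0 of 13 (12, 13, 10 and 2 over the list alone; 0.0453, 0.261, 0.103 and 0.367 with an estimated correlation). For ribosomal protein genes the counts were 0, 47, 0 and 0 of 81 (0, 71, 0 and 0 over the list alone; medians -0.45, -0.91, -0.45 and -0.36; 0.697, 0.261, 0.147 and 0.219 with an estimated correlation). For nuclear genes of oxidative phosphorylation they were 7, 53, 1 and 0 of 83, 83, 84 and 83 (20, 66, 6 and 0 over the list alone; 0.66, 0.207, 0.103 and 0.367 with an estimated correlation).

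**Figure D5:**
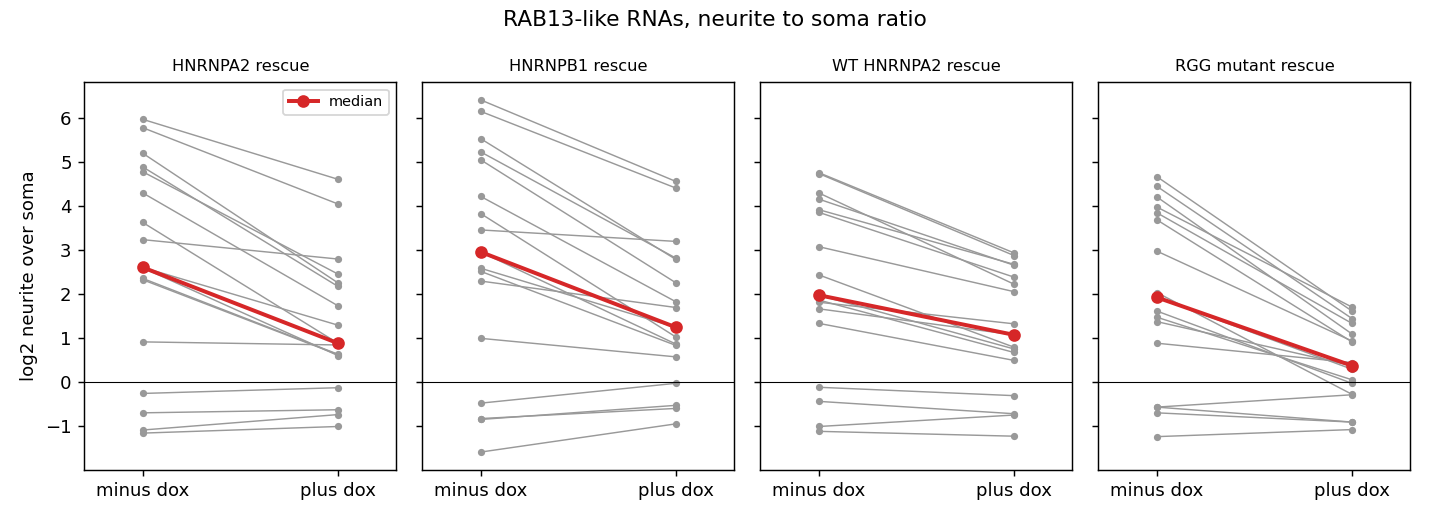
Log2 ratio of neurite to soma level without and with dox for each of the 17 Rab13-like peripheral RNAs (1 line per RNA), in 1 panel per rescue line, with the median in red. The medians go from 2.60 to 0.88 in A2, from 2.95 to 1.24 in B1, from 1.97 to 1.07 in WT and from 1.92 to 0.37 in RGG.

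Over all genes, the ratio changed for 518 in A2 (157 rose and 361 fell), 1757 in B1 (1009 and 748), 27 in WT (0 and 27) and 59 in RGG (1 and 58). It fell in 3 or more lines for 63 genes and in all 4 lines for 13, and rose in 3 or more lines for 0 (edgeR; the genes at an unadjusted p under 0.05 number 2505, 3554, 1041 and 629 in the 4 lines). The share that rose depended on the processing. With RLE scaling 76 rose and 374 fell in A2 and 611 and 862 in B1, and in 1 fit of all 48 libraries 3 and 229 in A2 and 142 and 429 in B1. With the replicate numbers as a block 705 rose and 562 fell in A2, and 1593 and 1095 (2688 in all) in B1. With DESeq2 the counts were 170 and 482 in A2 and 751 and 959 in B1. The number that rose in A2 was 50 without minus dox soma replicate 2 and 68 without each of plus dox soma replicates 2 and 3. It was 258, 67 and 261 without minus dox neurite replicates 1, 2 and 3 and 85 without plus dox neurite replicate 1. The B1 count was 1153 without minus dox neurite replicate 3, of which 633 rose. The WT count was 7, 2 and 8 without minus dox soma replicates 1, 2 and 3, and 13, 6 and 5 without plus dox soma replicates 1, 2 and 3. It was 14, 74 and 3 without minus dox neurite replicates 1, 2 and 3, and 88, 7 and 8 without plus dox neurite replicates 1, 2 and 3. The RGG count was 38 without minus dox soma replicate 1, 35 without plus dox soma replicate 3, 37 without minus dox neurite replicate 2, 36 without plus dox neurite replicate 1 and 114 without plus dox neurite replicate 3.

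Differences between the rescue lines were tested as differences of their dox effects. Between A2 and B1, 1 gene passed in soma: Arrdc3, an arrestin domain gene, whose dox effect was higher in A2 by a log2 difference of 1.17 ± 0.19 (edgeR adjusted p = 0.0275), with 1020 genes at an unadjusted p under 0.05. DESeq2 called 54, Arrdc3 not among them. In neurites 0 genes passed by edgeR, with 697 at an unadjusted p under 0.05 and 4 called by DESeq2. The ER chaperone list differed as a set in soma, with a median difference of 0.59 and 20 of 25 members higher in A2 adjusted over the list alone, though 0 passed among all genes (camera adjusted p = 5.2e-34, or 0.00466 with an estimated correlation). Cell cycle genes had a median difference of 0.71, with 0 of 36 past the threshold either over all genes or over the list alone (camera adjusted p = 1.5e-16, or 0.278 with an estimated correlation). The Hnrnpa2b1 effect differed by 0.09 ± 0.18 (adjusted p = 0.98) in soma and 0.45 ± 0.23 (1) in neurites. The soma count was 17 without A2 minus dox replicate 3, 15 without B1 plus dox replicate 3, and 2 without A2 plus dox replicate 1. It was 0 without each of A2 minus dox replicates 1 and 2, A2 plus dox replicates 2 and 3, B1 minus dox replicates 1, 2 and 3, and B1 plus dox replicates 1 and 2. In neurites it was 1 without A2 minus dox replicate 3.

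Between WT and RGG, 114 genes passed in soma, 61 with a higher and 53 with a lower dox effect in WT (47 and 71 with RLE scaling). The Hnrnpa2b1 effect differed by -0.50 ± 0.18 (edgeR adjusted p = 0.181) in soma and 0.02 ± 0.24 (1) in neurites. Dbh led, with a difference of 2.16 ± 0.32 (TMM-scaled CPM 58.6 to 20.9 in WT and 66.6 to 4.28 in RGG), followed by Optc (1.77 ± 0.29), Lrrn4 (1.59 ± 0.32), Nxph4 (1.35 ± 0.30) and Cxadr (1.26 ± 0.24). Lower in WT were Psd2 (-1.84 ± 0.26), the integrin gene Itgb3 (-1.16 ± 0.27), Rflnb (-1.15 ± 0.22), the potassium channel gene Kcnt1 (-1.14 ± 0.20), Npnt (-1.14 ± 0.22), Six4 (-1.04 ± 0.16) and the growth factor gene Fgf1 (-1.03 ± 0.17). Glycolysis and hypoxia genes had a median difference of 0.47, with 0 of 32 past the threshold over all genes and 5 higher in WT over the list alone (camera adjusted p = 5.7e-07, or 0.644 with an estimated correlation). Cholesterol synthesis genes had 0.38, with 3 and 10 of 24 (5.7e-07, or 0.644 with an estimated correlation). For ribosomal protein genes 4 of 81 were higher in WT and 19 over the list alone (1.0e-06, or 0.644 with an estimated correlation). In neurites 4 genes passed (1056 at an unadjusted p under 0.05). They include the antioxidant gene Srxn1 (-1.40 ± 0.26, edgeR adjusted p = 0.0483). The other 3 are predicted genes, named after their values were seen: Gm42742 (-2.07 ± 0.33), and Gm44848 and Gm49342, whose fitted folds rest on groups near 0 reads and are not given. The soma count was 15 without WT minus dox replicate 2, 59 without WT minus dox replicate 3, and 52, 60 and 69 without WT plus dox replicates 1, 2 and 3. It was 295, 67 and 246 without RGG minus dox replicates 1, 2 and 3, and 42 and 187 without RGG plus dox replicates 2 and 3. The neurite count was 18 without WT minus dox replicate 2, 1 and 0 without WT plus dox replicates 2 and 3, 1 without RGG minus dox replicate 3, and 11 and 9 without RGG plus dox replicates 1 and 3.

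The A2 and WT lines, both named for HNRNPA2, were compared in the same way after the data had been seen. In soma 5449 genes had different dox effects (2508 higher and 2941 lower in A2) and in neurites 3480 (1559 and 1921). The balance in soma turned with the processing, to 2840 higher and 2678 lower with RLE factors and 2870 and 2751 with DESeq2. Genes with a higher effect in A2 in soma included Rsad2 (6.50 ± 0.59), Lhfpl2 (5.32 ± 0.41) and 4 genes of the stress responses named above, with differences of 4.60 ± 0.20 for Ppp1r15a, 4.27 ± 0.29 for Atf3, 3.62 ± 0.18 for Ddit3 and 2.78 ± 0.21 for Hspa5. On the other side were Angpt2 (-3.88 ± 0.36), Pirt (-3.60 ± 0.21), Sgpp2 (-3.51 ± 0.31) and Igf2r (-2.96 ± 0.17). ER chaperone genes had a higher effect in A2 for 20 of 25 (21 over the list alone; adjusted p = 0.0667 with an estimated correlation). Cholesterol synthesis genes had a lower one for 23 of 24 (24 over the list alone; 0.0287 with an estimated correlation) and neuronal genes for 33 of 40 (34 over the list alone; 0.014 with an estimated correlation). The rise of Hnrnpa2b1 was larger in A2 by 0.59 ± 0.18 in soma (adjusted p = 0.0107) and 0.76 ± 0.24 in neurites (0.0218).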

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

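The tests for scaling, for genes near Adgrg1, for shared reads, for dox itself, for the level of induction and for line or culture batch were chosen after the results were seen, and so was the comparison of A2 with WT. The splits, the mixing test and the thinning test were planned before their results.

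The median neurite to soma ratio of the Rab13-like RNAs fell with dox in the 4 lines, though 11, 8, 5 and 4 of 17 members passed in A2, B1, WT and RGG, 2 rose in B1, and with an estimated correlation the camera call was lost in B1 (adjusted p = 0.261) and RGG (0.111). Scaling is argued against, since the list median minus the median of all genes was -1.79, -1.75, -1.21 and -1.68 in A2, B1, WT and RGG. Soma RNA mixed into the plus dox neurite fraction had a share estimated at 12.3, 26.4, 34.5 and 13.1 percent in A2, B1, WT and RGG. Over 15, 15, 16 and 15 members, mixing at that share predicted median changes of -0.04, -0.3, -0.4 and -0.1. The observed medians were -1.72, -1.65, -1.06 and -2.02. The unexplained median was -1.66, -1.37, -0.7 and -1.90. Its upper bounds from resampling the members were -0.17, -0.06, -0.35 and -0.81. All are negative, which argues against mixing at this share as the whole cause. Those of A2 and B1 missed the limit set beforehand, so mixing as a part of the cause stays open. The share came from genes low in neurites, picked by the same minus dox ratios, which can make it too high. In WT the shallowest library weighed as much as the others in it. Genes outside the list with a like ratio without dox fell as well (medians -1.76, -1.28, -1.22 and -1.88). They were picked by the same minus dox ratios that enter their change, which can make their fall too large. Whether the fall is particular to this list is therefore not decided. Dox itself cannot be told apart from the rescue protein, since each of the 24 plus dox libraries came from a line with a rescue, and an effect of the rescue protein stays open as untested.

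Adgrg1 rose with dox in the 4 lines. A spread of transcription that raises a neighbour in every line is argued against by the 8 genes within 250 kb with at least 1 CPM in soma. Of these 0 passed upward in all 4 lines. Ciapin1 did so in 3 lines, Cx3cl1, Coq9 and Polr2c in 2 and Dok4 in 1, so a weaker or partial spread stays open. Their highest log2 fold change was 1.71, for Cx3cl1, against at least 6.17 for Adgrg1. Reads of 1 transcript shared with Hnrnpa2b1 would give both genes the same neurite to soma ratio, but with dox that of Adgrg1 was lower by log2 differences of -1.22 ± 0.15, -1.1 ± 0.22, -1.70 ± 0.25 and -1.14 ± 0.27. Dox itself stays open here too, with 24 plus dox libraries that all carry a rescue. An element of the rescue construct that matches Adgrg1 was not tested, and a response of the gene to HNRNPA2B1 may be the biological alternative.

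The dox response called more genes in A2 than in WT or RGG. Depth is argued against for WT: with A2 libraries thinned to the WT depths, 7047 genes passed in soma and 5060 in neurites, against 1249 and 297 in WT, while thinning to the RGG depths was not run. Lower induction of the Hnrnpa2b1 RNA as the whole cause is argued against for RGG soma, where A2 minus RGG was 0.08 ± 0.19. The level of the rescue protein was not measured, so a lower protein level stays open. In WT soma and RGG neurites induction was lower (0.59 ± 0.18 and 0.78 ± 0.25). There 43.7 and 22.9 percent of the genes called in both lines went opposite to A2, which argues against a weaker copy of its response. Whether lower induction gives another kind of response was not tested, so it is not excluded there. Lower induction also stays open as a part of the cause, and for WT neurites (0.76 ± 0.24), where 6.17 percent went opposite. B1 neurites, however, called 5255 genes with a rise of 2.97 ± 0.18 beside 2.66 ± 0.19 in WT. Without dox A2 already differed from WT in 83 genes in soma and 241 in neurites, and from RGG in 2234 and 623, so the lines or their cultures were not alike. A2 and B1 were nearly alike, with 0 and 5 genes, while WT and RGG differed in 372 and 3, and B1 and RGG in 2885 and 1863. The bound of fewer than 100 genes in WT soma, though met, was wrong since it says nothing of the plus dox libraries. Line, batch and rescue protein cannot be told apart, and a difference between the rescue proteins may be 1 reading of several.

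Effects that differed between groups by a test of the difference itself follow. The effect of dox on Kif5b, Akap12 and other RNAs differed between neurites and soma, for 518 genes in A2 (highest of the other splits 3341, 2 of 40 splits as large), 1757 in B1 (2417, 2 of 40), 27 in WT (1020, 2 of 40) and 59 in RGG (949, 4 of 40). Chance cannot be excluded by these counts. In each of these lines the other splits as large left the dox labels of 1 fraction whole or mirrored and mixed or kept those of the other, so they hold the dox effect of a fraction, a structure of the samples. Arrdc3 was the 1 gene whose effect differed between A2 and B1 in soma (highest other 4892, 6 of 40 splits as large), and 0 differed in neurites by edgeR (697 at an unadjusted p under 0.05, 4 by DESeq2; highest other 2522, 40 of 40). Dbh, Psd2 and other genes, 114 in all, differed between WT and RGG in soma (highest other 1175, 7 of 40), and 4 did in neurites, Srxn1 among them (567, 5 of 40). Between A2 and WT, 5449 genes including Hspa5 differed in soma (highest other 4702, 1 of 40) and 3480 in neurites (4163, 6 of 40). The splits mix the dox labels within each line. In soma they can thus exclude chance only for a dox effect in these lines, not for a difference between the lines. The 4 highest others in soma, which kept the A2 labels whole, called 4554 to 4702, and without A2 plus dox replicate 3 the real count was 4697. In neurites chance cannot be excluded. Apart from A2 against B1 in neurites, where any split is as large as a count of 0, most of the other splits as large between lines left the dox labels of 1 line whole or mirrored, the same structure, but for WT against RGG some that mixed both lines were as large (440 genes in soma, 45 in neurites).

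For neurite against soma, chance can be excluded in each line: 8636 genes against 4337 for the highest other split in A2, 8486 against 5383 in B1, 6306 against 1207 in WT and 3730 against 100 in RGG, each with 1 of 40 splits as large. For dox within a line, the 10 splits of 6 libraries are too few for a share under 0.05. In soma the real counts and the highest others were 7203 and 0 in A2, 5766 and 1 in B1, 1249 and 0 in WT, and 1675 and 312 in RGG. In neurites they were 6278 and 0, 5255 and 0, 297 and 3, and 1435 and 273.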

How the results depend on the processing

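Leaving out the 2 libraries under 1 M reads, and the A2 against WT comparison, were chosen after seeing the data. No named gene reversed under an alternative. Of the calls of named genes, 1809 of 1838 held with RLE factors, 1809 of 1835 with DESeq2, 1772 of 1838 without the filter, 1790 of 1838 with the replicate block, 1662 of 1838 in 1 fit of all 48 libraries, and 1375 of 1426 without the 2 shallow libraries. Leaving out 1 library at a time kept 15541 of 16734. The cause of the changes below was not tested. In 1 fit of all 48 libraries, RGG localization had 6562 genes, WT dox 704 in soma and 545 in neurites, and the change of the ratio 232, 571, 46 and 255 in A2, B1, WT and RGG. That fit gave 0 and 2 genes for A2 against B1 and 44 and 48 for WT against RGG, in soma and neurites. It also gave fewer shared rises in soma (157 in 3 or more lines, 28 in all 4) and more in neurites (254 and 22). Without the filter, WT neurites had 634, the change of the ratio 837, 177 and 223 in A2, WT and RGG, A2 against B1 94 and 37, and WT against RGG 361 and 235. With the replicate block, the change of the ratio had 1267, 2688 and 93 in A2, B1 and WT, A2 against B1 in soma 8, and WT against RGG 172 and 27. With DESeq2, the change of the ratio had 78 in WT and 143 in RGG, A2 against B1 54 and 4, and WT against RGG 347 and 54. With RLE factors WT against RGG in neurites had 1. Without the 2 shallow libraries the change of the ratio in WT had 14 and A2 against B1 in soma 2. Camera made 206 list calls, without the A2 against WT comparison, and 32 with an estimated correlation. Leaving out each library in turn gave 702 to 916 for WT dox in soma, 98 to 455 for WT and 898 to 1441 for RGG in neurites. The change of the ratio ranged over 1153 to 1820 in B1, 2 to 88 in WT and 35 to 114 in RGG. A2 against B1 ranged over 0 to 17 in soma and 0 to 1 in neurites, and WT against RGG over 15 to 295 and 0 to 18. The libraries that moved a total count by more than 1.5 times are named with the results. Counts of rises or falls alone moved further for some other libraries. WT soma rises went from 593 to 373 without minus dox replicate 3, and WT neurite rises from 68 to 39 without plus dox replicate 1. RGG neurite falls went from 785 to 499 without plus dox replicate 2. In the 2 shallow libraries 3 reads are 41.5 and 6.57 CPM, so lower levels are not measured there.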

Other observations

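The 3' UTR test with lengths matched was chosen after the unmatched result was seen. Cell cycle genes fell in soma of B1, for 18 of 36 with 2 rising (21 and 3 adjusted over the list alone; camera adjusted p = 0.0218, or 0.77 with an estimated correlation). Mki67 (-1.14 ± 0.35), Top2a (-1.25 ± 0.36) and Ccnb1 (-1.34 ± 0.30) fell in B1. Of the same list 3, 0 and 1 fell in A2, WT and RGG and 6, 1 and 0 rose (3, 0 and 1 fell and 6, 0 and 0 rose over the list alone). The p53 targets rose for 7, 7, 0 and 0 of 19 in soma of A2, B1, WT and RGG and fell for 2, 3, 2 and 3 (the same counts over the list alone), with no camera call. Cdkn1a, a cell cycle inhibitor, rose in A2 and B1 (0.90 ± 0.16 and 1.43 ± 0.17) and fell in WT and RGG (-0.89 ± 0.17 and -1.03 ± 0.20). Of 12 nuclear-enriched long non-coding RNAs, 3 fell in WT soma, Neat1 (-2.11 ± 0.41) among them (6 over the list alone; camera adjusted p = 0.044 with an estimated correlation), and in A2, B1 and RGG 1, 2 and 2 fell and 3, 2 and 0 rose. Actin cytoskeleton genes fell in soma for 17 and 11 of 35 in A2 and B1 (17 and 14 over the list alone; 0.162 and 0.26 with an estimated correlation) and rose for 7 in WT and 5 in RGG, where 3 fell (in WT 8 over the list alone; 0.0575 with an estimated correlation). The intermediate filament gene Vim fell in A2 and B1 (-1.72 ± 0.09 and -1.45 ± 0.09). Mitochondrial ribosomal protein genes rose for 6 of 78 in WT soma (10 over the list alone; 0.201 with an estimated correlation).

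Among 27 hnRNP genes 4, 2, 0 and 1 rose in soma and 8, 9, 2 and 1 fell (4, 2, 1 and 1 rose and 7, 9, 2 and 1 fell over the list alone), with no camera call. Of 38 RNA localization and granule protein genes 9, 9, 5 and 3 fell and 9, 7, 0 and 3 rose (9, 9, 6 and 3 fell over the list alone; called in WT, with 0.542 with an estimated correlation). Of 28 splicing regulators 9, 5, 0 and 2 rose and 5, 6, 3 and 0 fell (9, 6, 0 and 1 rose and 5, 6, 3 and 0 fell over the list alone), with no camera call. Of 29 dynein and dynactin genes 4, 1, 0 and 3 rose and 6, 7, 2 and 2 fell (the same over the list alone), with no camera call. Of 20 myosins 4, 2, 3 and 5 rose and 7, 6, 2 and 0 fell (4, 2, 4 and 6 rose and 7, 6, 2 and 1 fell over the list alone), again with no camera call. Between the fractions, 16, 15, 12 and 9 dynein and dynactin genes were higher in neurites and 5, 6, 5 and 4 lower (6, 6, 5 and 5 lower over the list alone; camera adjusted p = 0.35, 0.511, 0.661 and 0.51 with an estimated correlation). In B1, 12 of 25 ER chaperone genes were lower in neurites and 1 higher (12 and 1 over the list alone), with a camera adjusted p of 0.113, and 0.017 with the replicate numbers as a block. Of 4 measured cargos with an A2RE-type element, 1, 1, 0 and 0 fell (the same over the list alone), with no camera call. In neurites the interferon response genes rose for 13 and 8 of 30 in A2 and B1 (13 and 8 over the list alone; 0.262 and 0.357 with an estimated correlation), and ATF4 targets for 14 and 16 of 28 (14 and 18 over the list alone; 0.262 and 0.0968 with an estimated correlation). Of 3 astrocyte markers 2, 2, 1 and 0 fell in soma (2, 2, 1 and 1 over the list alone), and of 4 oligodendrocyte markers 1, 1, 0 and 0 (1, 0, 0 and 0). Of 10 fibroblast markers 5, 5, 1 and 1 fell and 2, 1, 1 and 2 rose (5, 5, 3 and 2 fell and 2, 1, 3 and 2 rose over the list alone; called in B1, with 0.144 with an estimated correlation). Cd68, the only microglia marker measured, rose in A2 and B1 from 0.252 to 1.73 and from 0.185 to 1.02 CPM.

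Whether the 63 RNAs whose ratio fell in 3 or more lines carry more binding motifs was tested on the 60 with a 3' UTR, against 1298 others higher in neurites. UAG motifs did not differ past the threshold (medians 10.76 and 11.08 per kb, difference -0.32, permutation p = 0.743). GA-rich stretches were denser (1.59 and 0.5 per kb, difference 1.09, permutation p = 0.00888, adjusted 0.0178), but the 3' UTRs were also longer (medians 1545 and 411 nt). With lengths matched the difference was 0.24 (permutation p = 0.259), so length may account for the difference, and the test does not decide between the 2.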
